A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

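The samples were Myc immunoprecipitates and total chromatin from budding yeast with Myc-tagged Scc2 and degron-tagged Med14, from 3 cultures with and 3 without auxin. Per the labels' protocols, cells were held in alpha-factor for an additional 1.5 hours with auxin at 1 mM, released into nocodazole for 2 hours, mixed with fission yeast carrying Myc-tagged Mis4 at 1 to 4 for calibration, and fixed with formaldehyde for 30 minutes. The labels repeat this protocol, auxin included, for every sample. The cultures called without auxin here are those whose title and treatment label give none, and the comparison rests on those labels. Groups and replicate numbers were taken from the sample titles. The labels describe a separate culture for each replicate, and all samples share a genotype, so an effect of auxin itself and an effect of Med14 loss are not separated by this comparison. No list from cells lacking the tag or the degron was used here.

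The authors deposited a list of narrow peaks for each immunoprecipitate. Per the submitters' processing notes, reads were handled with Bowtie2 2.4.2 and MACS2 2.1.1.20160309 on the sacCer3 build. The role of each tool, the threshold and the use of total chromatin as control are not given in the sources used here. Lists are separate for each replicate. The fold enrichment in each list is a ratio that the authors' peak caller gave, and the significance columns are −log10 p and −log10 q values as deposited by the authors. The smallest −log10 q was 2.31 to 2.76 over the 6 lists. The positions and summit offsets are deposited in base pairs. Significance was used to rank or filter peaks within a list. Fold was used to choose the regions and genes to name, as a median over lists, and the median fold of each list was used to describe the lists and, in the closing section, to find pairs of lists with similar enrichment. No change in Scc2 was read from fold. Averaged signal tracks were not used here, so calibration by fission yeast does not enter any value, and a region without a peak is one where none was called, not one without Scc2. The number of peaks called moves with depth and enrichment, which are unknown, and a deeper or better enriched library gives more peaks at weak sites.

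Genes were taken from a RefSeq table of assembly R64, the sequence that sacCer3 uses, which gives positions and kinds of genes. The strand of all 6002 nuclear coding genes was read from their systematic names. The positions of the 16 centromeres and the chromosome lengths were not in that table and were entered from general knowledge of the genome. They were checked only in that no centromere overlapped an annotated gene and no peak passed a chromosome's end, and their coordinates are not reported.

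A peak was placed at a coding gene when it overlapped, by 1 base or more, the coding sequence or the 250 bp upstream of its start, and at a small RNA gene or centromere when it overlapped the feature or 250 bp on either side. Coding sequence here means the annotated span of a coding gene, introns included. Peaks of all lists were merged into regions where they overlapped by 1 base or more. The number of peaks and covered length were compared with an exact two-sided permutation test of the difference of means over 20 assignments, whose smallest p is 0.1. The share of members with a peak was compared in the same way for each of 20 classes, with Benjamini-Hochberg adjustment. Features with a peak in at least 2 of 3 lists without auxin were followed to the lists with auxin, and each class with 5 or more such members was compared with coding genes outside every class by a two-sided Fisher's exact test, adjusted over 14 classes. The threshold was an adjusted p of 0.05. Tests over genes treat neighbours that share a peak as separate, so their p-values are too small.

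The classes, tests, windows, alternatives and the rule for naming genes were fixed before the data were examined. The rule named the MED14, SCC2 and ADH1 loci, up to 10 lost, kept and gained regions with the highest median fold (over the lists without auxin for lost and kept regions and those with auxin for gained regions), and for each class with enough members the 2 kept and the 2 lost members with the highest median fold without auxin. Some items that the rule named are not reported here. All but 1 of the listed genes were found in the table, ARG5,6 being unmatched, so that 20 of 21 amino acid biosynthesis genes were used. HTA1, HTB1 and HHF2, and the genes named in the closing section for peaks in lists with auxin, were chosen after their values were seen. Coverage of coding sequences, coverage by position, at 4 offsets for 2 classes, and the placement of summits were also added after seeing the data, as were the alternatives with 4 lists and with coding genes at least 1000 bp from tRNA genes and centromeres.

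The alternatives, each for the results it applies to among number of peaks, covered length, regions, class occupancy and share kept, were a −log10 q of at least 5, lists cut to the 964 peaks with the largest −log10 p, each list left out in turn, exclusion of the mitochondrial genome, the ribosomal DNA and 20 kb at each chromosome end, regions covered to at least 50%, windows of 100 bp around summits, 2 of 3 lists per group, gene windows of 0 or 500 bp, summits within the window, 1 feature per peak, and the replicate number as a block. Peak width and coverage of coding sequences, by position and of the mitochondrial genome were not recomputed under them. With a list left out, the share kept still required a peak in at least 2 lists of a group, hence in both that remained. The procedure was tested on simulated data for this comparison. In 2769 simulated regions it recovered 100% of 300 lost, 100 gained and 500 kept regions. Each was placed in exactly the lists that its state requires, so this recovery checks the code and no more. The changed class was called in 100 of 100 draws, and 0.354% of unchanged classes were called. These draws held identical lists within a group and independent genes, so 0.354% is not an error rate for the real lists. Other splits of the real lists called 3 to 6 classes. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.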

Results

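Binding of Scc2, the subunit of the Scc2-Scc4 complex that loads cohesin onto chromosomes, was mapped by chromatin immunoprecipitation and sequencing in budding yeast of the W303 background. Scc2 carried a Myc tag. Med14, the scaffold subunit of the Mediator coactivator of RNA polymerase II, carried an auxin-inducible degron, which the plant F-box protein OsTIR1 marks for degradation once auxin is added. The comparison between cultures with 1 mM auxin and cultures without auxin addressed where Scc2 was found on the genome after auxin was added to deplete Med14. Cells were arrested with alpha-factor and then released into nocodazole for 2 hours to arrest them in mitosis, per the labels' protocols. The cell-cycle stage was not measured here. Of the 12 samples, 6 were Myc immunoprecipitates with a peak list each (3 cultures with and 3 without auxin), and the 6 total chromatin samples have no list of their own. The lists held 9585 peaks in all. Without auxin they held 2115, 2111 and 1502 peaks, and with auxin 964, 1324 and 1569 peaks. The sequencing depth behind the lists is unknown, and each list reports only whether a peak was called, so the values below are positions and counts of peaks and not amounts of Scc2. All coordinates are on sacCer3. No 2 lists shared a peak with the same start and end.

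Scc2 peaks covered less of the genome in cultures with auxin. The covered length was 1332 ± 158 kb without auxin (SD, n = 3) and 789 ± 169 kb with auxin (SD, n = 3), and no list of either group overlapped the other group. The exact two-sided permutation test gave p = 0.1 for covered length, which is the smallest value that 3 lists against 3 can give. The difference (auxin minus no auxin) was -543 kb, and -280 kb with 964 peaks in every list. The number of peaks was 1909 ± 353 without and 1286 ± 304 with auxin (SD, n = 3 each; exact permutation p = 0.2), and the groups overlapped, at 1502 peaks in a list without and 1569 in a list with auxin. Peaks had a mean width of 704 ± 53.0 bp without and 618 ± 39.8 bp with auxin (SD, n = 3 each; exact permutation p = 0.1). Over the 15 pairs of lists, the Jaccard index of covered bases was 0.593 to 0.741 among the lists without auxin and 0.518 to 0.657 among those with auxin. It was 0.268 to 0.442 between groups, so that each list had a higher index with both lists of its own group than with any list of the other. The third list without auxin stood apart from the other two, with fewer peaks and a median fold enrichment, as the authors' peak caller gave it, of 2.54 against 1.70 and 1.67. The lists with auxin had median folds of 3.93, 2.83 and 2.57.

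Merging the peaks of all 6 lists gave 2769 regions. Peaks at snoRNA and ribosomal protein genes were among those missing with auxin, whereas peaks at tRNA genes and centromeres were found in both conditions. All 3 lists without auxin and no list with auxin held 350 regions, here called lost. None of these 350 lay at a tRNA gene or centromere, and 41 lay at a snoRNA or snRNA gene. All 6 lists held 523 regions, here called kept, of which 263 lay at a tRNA gene and 16 at a centromere, and 9 at a snoRNA or snRNA gene. All 3 lists with auxin and no list without it held 103 regions, here called gained, of which 1 lay at a tRNA gene and 10 within 20 kb of a chromosome end. The remaining 1793 regions were held by other combinations of lists. The counts of lost and gained regions depended on which lists had to agree: without the third list lacking auxin, 761 regions were lost and 156 gained, and without the first list with auxin 203 were gained. Fewer regions were lost with lists of equal length.

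The 10 lost regions that ranked highest by the authors' fold enrichment included 5 named for snoRNA genes, which encode guides for the modification and processing of ribosomal RNA. These were the regions at SNR40 (chromosome XIV, 89033 to 89778), SNR9 (chromosome XV, 407481 to 408195), SNR10 (chromosome VII, 345914 to 346718), SNR11 (chromosome XIII, 652241 to 653071) and SNR17B (chromosome XVI, 280515 to 281488). Others lay at the ribosomal protein genes RPL30 and RPS4B. Peaks covered 80.0 ± 14.4% of the RPL30 coding sequence without auxin (SD, n = 3) and none of it in any list with auxin. The same holds for RPS4B, at 78.3 ± 0.954% without auxin (SD, n = 3). Another 2 were at YHB1, the nitric oxide-scavenging flavohaemoglobin, whose coding sequence was covered in full in each list without auxin and uncovered in each list with it, and at EFM3, a lysine methyltransferase gene whose region also touched a small RNA gene. At YHB1, 1 list with auxin held another peak in the gene's window, outside the lost region.

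The 10 kept regions that ranked highest by fold without auxin lay at RNA polymerase III genes, at a centromere and at genes of glycolysis and translation. The highest lay on chromosome V from 441829 to 442725 and takes its name, YER137C, from the neighbouring coding gene, but its peaks covered SCR1, the RNA of the signal recognition particle. Another lay at the tRNA gene YNCJ0012W on chromosome X (355237 to 355850). The region named for YPT7 on chromosome XIII held a centromere. The other 7 lay at TDH2, TDH3, ADH1, TEF1, ENO2, PGK1 and CDC19. At TDH3, a glyceraldehyde-3-phosphate dehydrogenase gene on chromosome VII, peaks covered 100% of the coding sequence in each list without auxin and 82.4 ± 11.1% with auxin (SD, n = 3). At CDC19, the pyruvate kinase gene, the coverage was 100% in each list without auxin and 56.4 ± 39.1% with auxin (SD, n = 3). TDH2 and TDH3, and likewise TEF1 and TEF2, are near-identical copies whose reads the aligner can exchange, so their peaks are uncertain as separate observations.

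The 10 gained regions that ranked highest by fold lay at SPT8, ENV9, YPL062W, YLR108C, YOR343C, YBL044W, GIC2, PCL1 and GTT3 and at a place on chromosome XV (978446 to 979690) with no annotated feature. For ENV9, GIC2, PCL1 and GTT3 the peaks did not reach the coding sequence in any list. At PCL1, a G1 cyclin gene on chromosome XIV, the gained region spanned 87344 to 87781, upstream of the coding sequence that starts at 87897. SPT8 encodes a subunit of the SAGA coactivator, and peaks covered 22.3 ± 20.8% of its coding sequence with auxin (SD, n = 3). A single list without auxin held another peak at SPT8 outside the gained region.

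**Figure D1:**
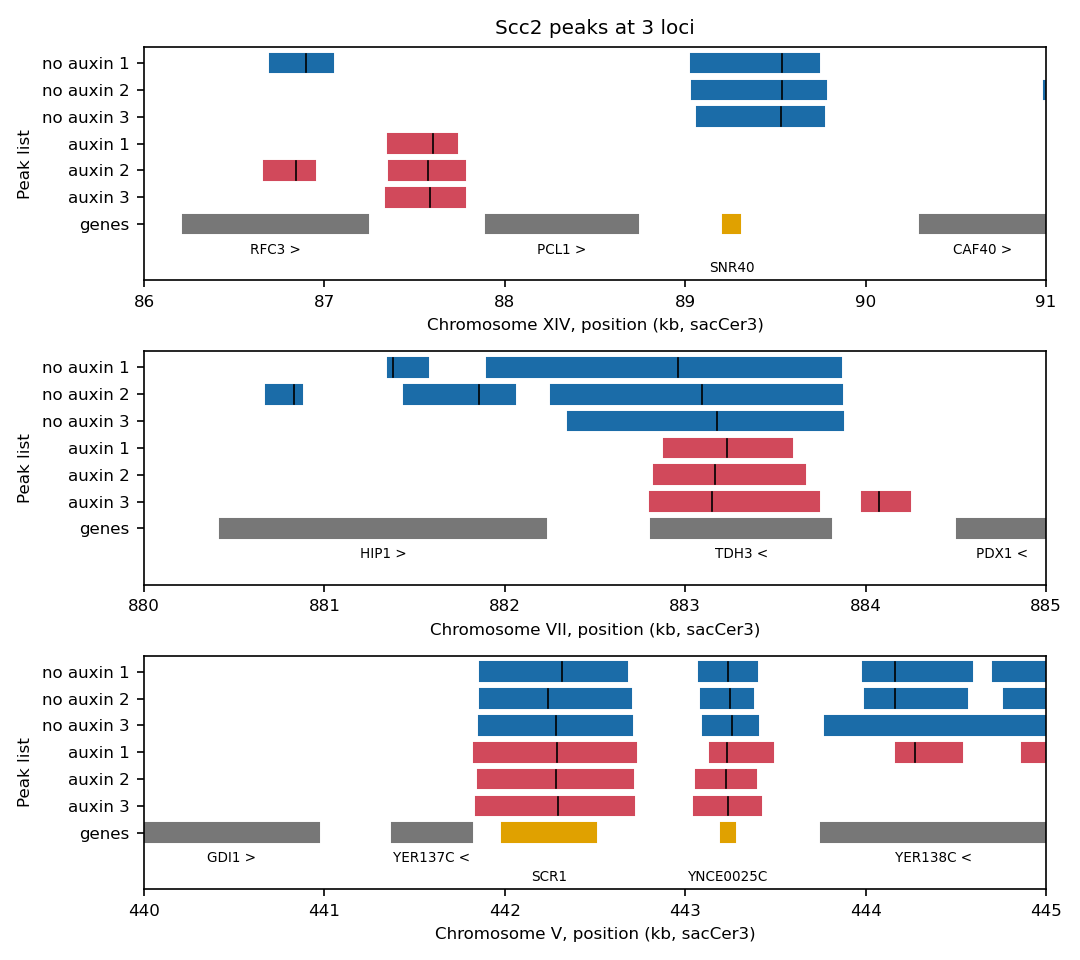
Peaks of the 6 lists at 3 loci (horizontal axis: position in kb, sacCer3; vertical axis: 1 row per list, blue without and red with auxin; black ticks: summits; grey: coding genes with their direction; orange: small RNA genes). The SNR40 peak was present in the 3 lists without auxin and absent in the 3 with it, the peak upstream of PCL1 showed the opposite, TDH3 kept a narrower peak, and the SCR1 peak was found in all 6 lists.

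Peaks at tRNA genes, centromeres and other RNA polymerase III genes were present with and without auxin. Of the 275 nuclear tRNA genes, 98.8 ± 0.555% had a peak without auxin and 98.2 ± 1.89% with auxin (SD, n = 3 each; exact permutation p = 1). Each of the 16 centromeres had a peak in all 6 lists. Of the 5 other RNA polymerase III genes, which include SCR1 and the RNase P RNA gene RPR1, all had a peak in each list without auxin, and 3, 5 and 5 had one with auxin (exact permutation p = 1). Of the features with a peak in at least 2 lists without auxin, 272 of 272 tRNA genes and 16 of 16 centromeres also had one in at least 2 lists with auxin. Among coding genes outside every list, 618 of 1243 did, or 49.7%. For such genes at least 1000 bp from tRNA genes and centromeres it was 383 of 978, or 39.2%, since a neighbour's peak can count for a coding gene. By Fisher's exact test with Benjamini-Hochberg adjustment over 14 classes, the shares of tRNA genes and centromeres differed from the 49.7% of other coding genes (adjusted p = 2.96e-71 for tRNA genes and 0.00013 for centromeres). The 5 other RNA polymerase III genes were also all kept, with an adjusted p of 0.0615 by the same Fisher's exact test. Here the genes, not the cultures, are the units, and neighbouring genes share peaks. Nearly all tRNA genes and all centromeres had a peak in each of the 6 lists. Their shares kept would therefore be near 100% however the lists were grouped, and these p-values do not measure an effect of auxin.

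Small nucleolar and ribosomal protein genes had fewer peaks with auxin. Of the 82 snoRNA and snRNA genes, 78, 78 and 71 had a peak without auxin, against 7, 13 and 21 with auxin, or 92.3 ± 4.93% and 16.7 ± 8.57% (SD, n = 3 each; exact permutation p = 0.1, adjusted 0.2). Only 12 of 78 that had a peak in at least 2 lists without auxin kept it, a smaller share than among other coding genes (15.4% against 49.7%, Fisher's exact test, adjusted p = 9.48e-09). The 12 include SNR6 and SNR52, which were also counted among the other RNA polymerase III genes. With each peak assigned to 1 feature, the difference in occupancy (auxin minus no auxin) went from -75.6 to -41.9 percentage points and that in the share kept from -34.3 to -20.8. SNR30, needed for pre-ribosomal RNA processing, kept its peak in 3 of 3 lists with auxin and SNR17A in 2 of 3, while SNR128 and SNR190, which lie side by side on chromosome X and shared their peaks, had one in 1 of 3. Of the 138 ribosomal protein genes, 133, 131 and 124 had a peak without auxin, against 17, 53 and 83 with auxin, or 93.7 ± 3.42% and 37.0 ± 23.9% (SD, n = 3 each; exact permutation p = 0.1, adjusted 0.2). RPS31 and RPL14B were among the 55 of 130 that kept a peak, and RPS12 was among the 75 that did not. RPL14B lies beside a centromere, whose peak it shares.

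The share of ribosomal protein genes that kept a peak, 42.3%, did not differ from that of other coding genes (Fisher's exact test, adjusted p = 0.182). That outcome depended on the rule for a peak at a gene. When a peak had to overlap the coding sequence itself, 22 of 130 kept one, or 16.9%, against 40.6% of other coding genes (Fisher's exact test, adjusted p = 2.4e-07). With lists of equal length the adjusted p by Fisher's exact test was 4.19e-13. Leaving out the first or second list without auxin gave an adjusted p of 1.8e-05 each, and leaving out the second or the third list with auxin gave 1.59e-08 and 1.87e-09. By the same Fisher's exact test it was 0.217 without the third list lacking auxin and 0.169 without the first list with auxin. With a list left out, a peak was required in both remaining lists of that group. Assigning each peak to 1 feature turned the difference to 1.36 percentage points above other coding genes, with an adjusted p of 0.768. At least 1000 bp from tRNA genes and centromeres, 54 of 127 kept one, or 42.5%, against 39.2% of other coding genes (Fisher's exact test, adjusted p = 0.5). Over 15 alternatives the adjusted p ranged from 4.19e-13 to 0.768, and 7 passed the threshold of 0.05.

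**Figure D2:**
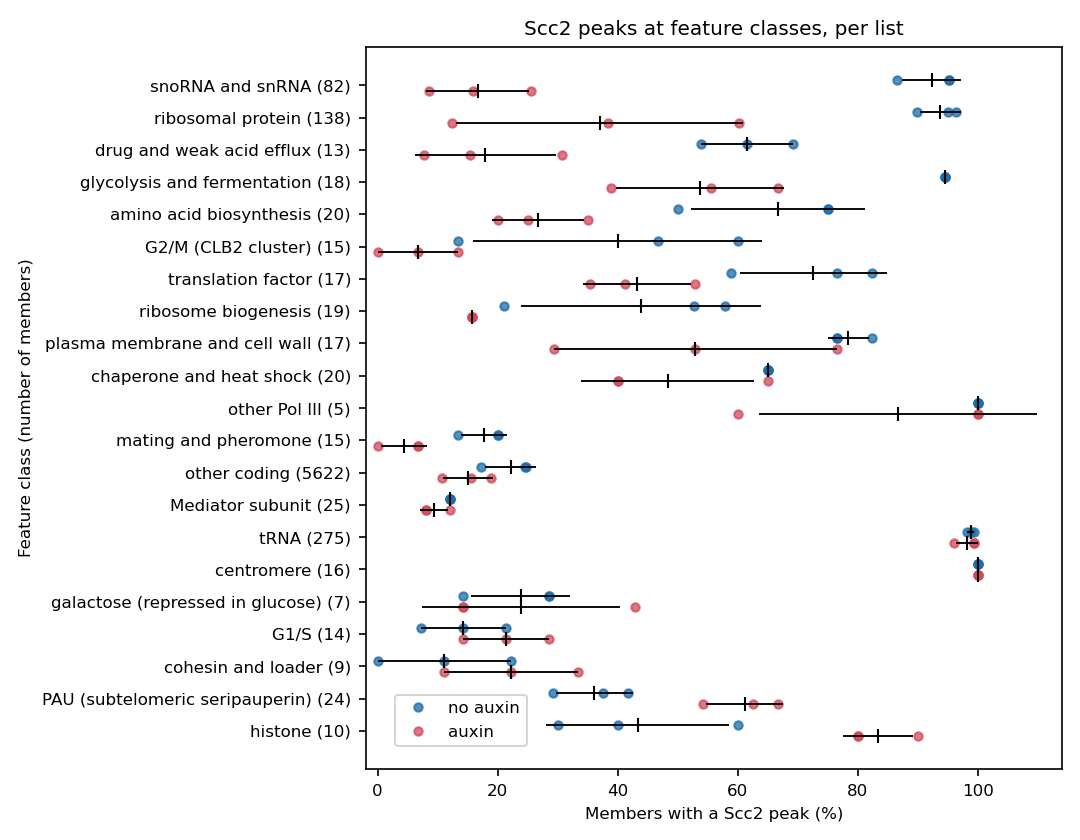
Share of members with a Scc2 peak (horizontal axis, %) for each class of genes or features (vertical axis, number of members in brackets), with 1 point per list, blue without and red with auxin, the black tick and bar giving mean and SD of 3 lists. The snoRNA and snRNA class went from a mean of 92.3% without to 16.7% with auxin, while the tRNA class stayed at 98.8% and 98.2% and the centromeres at 100%. A bar can extend past 100% because it is symmetric.

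Several other groups of RNA polymerase II genes had peaks at fewer members with auxin. Of 18 genes of glycolysis and fermentation, 17 had a peak in each list without auxin, against 7, 10 and 12 with auxin (exact permutation p = 0.1, adjusted 0.2). TDH2 and TDH3 kept theirs, and TPI1 and ENO1, for triose phosphate isomerase and enolase, had one in 1 of 3 lists with auxin. Of 17 translation factor genes, 72.5 ± 12.2% had a peak without and 43.1 ± 8.99% with auxin (SD, n = 3 each; exact permutation p = 0.1, adjusted 0.2). TEF1 and TEF2, the elongation factor 1-alpha genes, kept theirs, TIF2 had none with auxin and TEF4 had a peak in 1 of 3 lists. Of 20 amino acid biosynthesis genes, 66.7 ± 14.4% had a peak without and 26.7 ± 7.64% with auxin (SD, n = 3 each; exact permutation p = 0.1, adjusted 0.2). ILV5 and LEU2 kept theirs, although LEU2 lies beside a tRNA gene, and ASN1 and SER3 did not. Of 19 ribosome biogenesis genes, 10, 11 and 4 had a peak without auxin and 3 in each list with it (exact permutation p = 0.1, adjusted 0.2). NOP1 and NSR1 kept theirs, and NOP58 and CBF5 had none with auxin. With 964 peaks in every list, the groups overlapped in the amino acid and ribosome biogenesis classes, at 9, 10 and 6 against 4, 5 and 7 members and at 3, 5 and 3 against 3, 3 and 2 members. None of the 4 classes differed from other coding genes in the share kept by Fisher's exact test, which was 9 of 17 for glycolysis and fermentation (adjusted p = 0.812), 7 of 12 for translation factors (0.705), 4 of 15 for amino acid biosynthesis (0.182) and 2 of 9 for ribosome biogenesis (0.25). For amino acid biosynthesis the adjusted p was 0.0247 when peaks had to overlap the coding sequence.

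Among drug and weak acid efflux genes and the G2/M genes of the CLB2 cluster, no gene with a peak in at least 2 lists without auxin had one in at least 2 lists with it, although the efflux genes FLR1 and PDR15, named after their values were seen, had one in at least 2 lists with auxin and in at most 1 list without. Efflux genes had a peak at 8, 9 and 7 of 13 members without and at 1, 2 and 4 with auxin (exact permutation p = 0.1, adjusted 0.2). None of the 8 with a peak in at least 2 lists without auxin kept it (Fisher's exact test, adjusted p = 0.0215). These included PDR5 and SNQ2, which encode multidrug transporters, and peaks covered 72.1 ± 14.2% of PDR5 without auxin and none of it with auxin (SD, n = 3). G2/M genes had a peak at 7, 9 and 2 of 15 members without and at 0, 1 and 2 with auxin (exact permutation p = 0.2, adjusted 0.364). None of the 7 with a peak in at least 2 lists without auxin kept it (Fisher's exact test, adjusted p = 0.0359), among them CDC5, the polo kinase gene, and HST3. With 964 peaks in every list the differences in occupancy were small, at 2, 3 and 3 efflux genes without against 1, 2 and 3 with auxin and at 1, 1 and 0 against 0, 1 and 0 G2/M genes. Both calls by Fisher's exact test depended on the setting, and 8 of 14 alternatives passed for efflux genes and 6 of 12 for G2/M genes. Without the second or the third list with auxin, a gene counted as kept only with a peak in both remaining lists. Fewer other coding genes then counted as kept, and still none of either class. The differences were -37.9 and -37.5 percentage points in each class, against -49.7 with all lists. The adjusted p by Fisher's exact test was 0.0657 and 0.0676 for efflux genes and 0.099 and 0.101 for G2/M genes. Windows of 500 bp ended the efflux call, at 2.03 percentage points above other coding genes.

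The remaining classes showed smaller or overlapping differences. Chaperone and heat shock genes had a peak at 13 of 20 members in each list without auxin and at 8, 8 and 13 with it (exact permutation p = 0.4, adjusted 0.571). SSA1 and SSB2 kept theirs, and HSC82 and YDJ1 had one in 1 of 3 lists with auxin. Of chaperone genes at least 1000 bp from tRNA genes and centromeres, 7 of 13 kept one, so a neighbour's peak can count as kept here. Plasma membrane and cell wall genes had one at 13, 13 and 14 of 17 members without and at 5, 9 and 13 with auxin (exact permutation p = 0.3, adjusted 0.5). CCW12 and HSP150 kept theirs, and EXG1 and SCW4 had none with auxin. By Fisher's exact test the kept shares of these classes, 8 of 14 and 7 of 13, did not differ from that of other coding genes (adjusted p = 0.705 and 0.812). Mating and pheromone genes had a peak at 2, 3 and 3 of 15 members without and at 0, 1 and 1 with auxin (exact permutation p = 0.1, adjusted 0.2), and at equal list length at 1, 1 and 0 against none. Mediator subunit genes had one at 3, 3 and 3 of 25 members without and at 2, 3 and 2 with auxin (exact permutation p = 0.4). Galactose genes, which glucose represses, had one at 1, 2 and 2 of 7 members without and at 1, 1 and 3 with auxin (exact permutation p = 1).

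Histone genes and the subtelomeric seripauperin genes of the PAU family had peaks at more members with auxin. Of 10 histone genes, 6, 4 and 3 had a peak without and 8, 8 and 9 with auxin (exact permutation p = 0.1, adjusted 0.2). HTA1 and HTB1, a divergent pair on chromosome IV, and HHF2 on chromosome XIV had no peak in any list without auxin and one in 3 of 3 lists with auxin. Divergent histone pairs share the peak between them, and the difference turned to 30.0 percentage points fewer members with auxin when the summit had to lie within 1 gene window, and was 6.67 points higher with auxin when each peak was assigned to 1 feature. Of 24 PAU genes, 10, 9 and 7 had a peak without and 13, 16 and 15 with auxin (exact permutation p = 0.1, adjusted 0.2). All 9 with a peak in at least 2 lists without auxin, PAU1 and PAU14 among them, kept it (Fisher's exact test, adjusted p = 0.0133). Without the first or the second list lacking auxin that adjusted p was 0.192 and 0.207. PAU genes are near-identical copies at chromosome ends, so their peaks are uncertain. G1/S genes had a peak at 2, 3 and 1 of 14 members without and at 2, 3 and 4 with auxin (exact permutation p = 0.5), and genes of cohesin and its loader at 2, 1 and 0 of 9 without and at 1, 2 and 3 with auxin (exact permutation p = 0.5).

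Over the 20 classes, 14 had a lower mean share with auxin and 4 a higher one. In 10 classes the 2 groups of lists did not overlap, each at the smallest p the exact permutation test can give. Chance gives 10% of classes on average, but all classes were scored on the same 6 lists and can separate together. The 10 classes are therefore not independent results. No class passed the threshold after adjustment, which this design cannot reach. By Fisher's exact test 6 of 14 classes differed from other coding genes in the share kept, and each other split of the 6 lists gave 3 to 6 such classes. Of all 6002 nuclear coding genes, 1489 had a peak in at least 2 lists without auxin, 728 of these also had one in at least 2 lists with auxin, and 227 others had one in at least 2 lists with auxin and in at most 1 without.

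Within the coding sequences, peaks covered less with auxin in most of the classes examined. This measure was chosen after the data had been seen. Peaks covered 71.0 ± 9.0% of ribosomal protein coding sequence without auxin and 7.96 ± 5.66% with auxin (SD, n = 3 each; exact permutation p = 0.1). They covered 88.8 ± 1.39% and 34.5 ± 15.1% for glycolysis and fermentation genes (SD, n = 3 each; exact permutation p = 0.1). For PAU genes the coverage was higher with auxin, at 48.6 ± 7.46% against 28.8 ± 5.35% (SD, n = 3 each; exact permutation p = 0.1). For histone genes it was 35.7 ± 10.9% without and 30.6 ± 19.2% with auxin (SD, n = 3 each; exact permutation p = 0.8), a difference within the spread between lists. At 500 bp into the ribosomal protein genes, 81.6 ± 9.84% of genes were covered without and 8.94 ± 6.25% with auxin (SD, n = 3 each; exact permutation p = 0.1). That position lies past the end of shorter genes such as RPS12 and RPS31. At 300 bp upstream of the start codon the order was the opposite, with 6.28 ± 0.418% without and 25.8 ± 17.8% with auxin (SD, n = 3 each; exact permutation p = 0.1), whereas at 250 bp upstream the exact permutation p was 0.2.

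**Figure D3:**
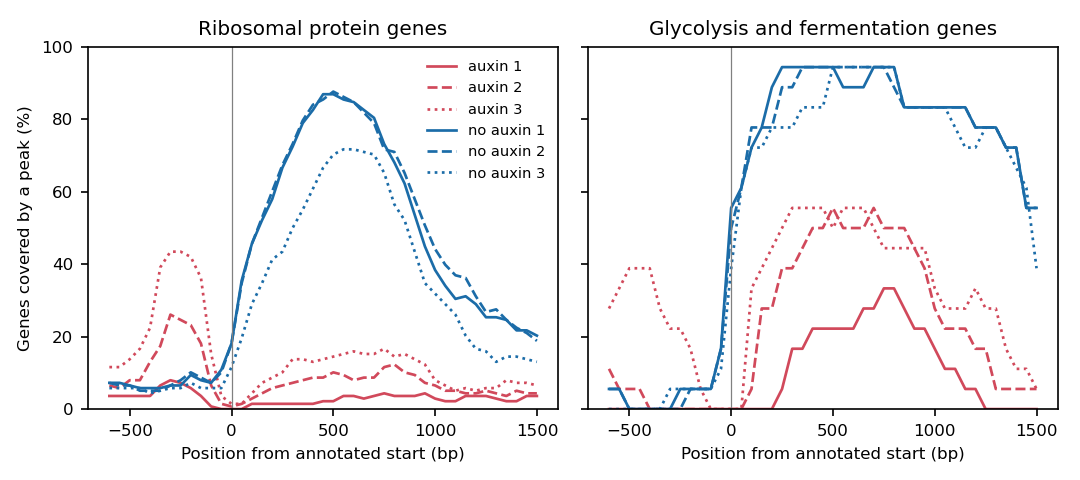
Percentage of ribosomal protein genes (left) and glycolysis and fermentation genes (right) covered by a peak (vertical axis) against the position from the annotated start codon in bp (horizontal axis), with 1 line per list, blue without and red with auxin. At 500 bp the mean over ribosomal protein genes was 81.6% without and 8.94% with auxin, and the rise upstream of the start appears in the second and the third list with auxin more than in the first.

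The loci that the strain alters were examined in each list. The MED14 gene, annotated as RGR1 on chromosome XII (275378 to 278626), had a peak in its window in 1 list without auxin and in 2 lists with auxin. SCC2 on chromosome IV (821295 to 825776) had none in any of the 6 lists. ADH1 on chromosome XV (159548 to 160594), whose promoter drives OsTIR1 in the strain, had a peak in all 6 lists, which covered 100% of its coding sequence in each list without auxin and 72.3 ± 23.1% with auxin (SD, n = 3). Peak positions show nothing of Med14 protein, so the depletion itself was not measured here.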

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

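The mitochondrial genome was summarised after the data had been seen, because no class comparison uses it. Peaks were called over a median of 53.4% of its length across the 6 lists. Without auxin 65, 65 and 64 peaks covered 41.3, 37.1 and 52.8% of it, and with auxin 24, 59 and 59 peaks covered 92.0, 54.0 and 59.6%. The covered share was 43.7 ± 8.11% without and 68.5 ± 20.5% with auxin (SD, n = 3 each; exact permutation p = 0.1, the smallest possible). No explanation was tested. Without a list from untagged or no-antibody samples, the lists do not show whether these mitochondrial peaks come from Scc2.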

How the results depend on the processing

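The alternatives with 4 lists and with coding genes away from tRNA genes and centromeres were chosen after seeing the data. Lower numbers of peaks and lower covered length with auxin held in all 10 and 11 alternatives, and the calls for tRNA genes, centromeres and snoRNA genes by Fisher's exact test held in all 15, 14 and 15. For tRNA genes and centromeres the shares kept follow from peaks at nearly all of these features in every list, with or without auxin. Covered length differed by -280 kb in equal-length lists. With 1 feature per peak the difference in share kept was -20.8 for snoRNA genes (Fisher's exact test, adjusted p = 0.0212, from 8.09e-17 to 0.0212 over the alternatives), and occupancy differed by -41.9 for these and 6.67 for histone genes. Differences in the share kept, against other coding genes and in percentage points, changed as follows, and the cause was not tested unless stated. Over 16 alternatives each, occupancy differences (auxin minus no auxin) ranged from -51.7 to -15 for amino acid, -39.5 to -5.26 for ribosome biogenesis, -50 to -5.13 for efflux and -46.7 to -2.22 for G2/M genes, and in equal-length lists they were -15, -5.26, -5.13 and -2.22. With a −log10 q of at least 5, ribosomal protein genes passed at -15.8, glycolysis turned to -0.0344, and the occupancy difference (auxin minus no auxin) of Mediator subunits turned to 1.33. In equal-length lists, ribosomal protein genes passed at -36.3, chaperones turned to -20.9, glycolysis to -18.3, membrane and cell wall genes and translation factors to -5.36 each, and Mediator occupancy to 5.33. With no window, ribosomal protein genes passed at -23.7 and amino acid genes at -33.5, G2/M genes no longer passed at -40.6, and occupancy turned to -3.33 for histone genes and to 6.67 for other RNA polymerase III genes. With summits in the window, G2/M and efflux genes no longer passed at -36.1 each, and occupancy turned to 1.33 for Mediator, -30.0 for histone and 6.67 for other RNA polymerase III genes. With 1 feature per peak, G2/M and efflux genes no longer passed at -37.0 each, ribosomal protein genes turned to 1.36, RPS31 occupancy to 33.3 and other RNA polymerase III occupancy to 26.7. With windows of 500 bp efflux genes turned to 2.03. Away from tRNA genes and centromeres, G2/M and efflux genes no longer passed at -39.2 each, other RNA polymerase III genes passed at 60.8, and ribosomal protein genes turned to 3.36.

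Lost regions numbered 197 in equal-length lists, which hold fewer peaks, 775 with 2 of 3 lists and 783 with 4 lists (the first and the second without and the second and the third with auxin), where fewer lists must agree. Gained regions numbered 218 with 2 of 3 lists and 268 with 4, and kept regions 319 when at least 50% of a region had to be covered. With 4 lists tRNA occupancy turned to 0.727. Leaving out each list in turn gave 361 to 761 lost, 105 to 203 gained and 530 to 664 kept regions. It gave shares kept of -49.3 to -37.5 for G2/M, 35.4 to 62.5 for PAU, -64.6 to -37.5 for efflux, -26.0 to -6.97 for ribosomal protein, -6.25 to 12.5 for chaperone, -11.6 to 4.11 for glycolysis and -10.7 to 9.05 for membrane and cell wall genes, and a tRNA occupancy difference of -1.15 to 0.485. Among these runs, the highest lost count came without the third list lacking auxin, and the highest gained count without the first list with auxin.

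With the replicate number as a block, an exact sign-flip test whose smallest p is 0.25, the difference in peaks was -624 (p = 0.5) and in covered length -543 kb (p = 0.25). Deviations of same-numbered lists correlated at r = 0.0477, 0.0083 and 0.115 across regions, and the second list without auxin correlated more with the first list with auxin (0.0839), so the numbers were not taken as pairs. No class passed a threshold under the block, nor could any. Depth is unknown, and 3 lists against 3 cannot pass 0.05 in any exact permutation test. PAU genes were not tested without repeats and chromosome ends, where they lie, and classes that fell below 5 members gave no Fisher's exact test.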

Other observations

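The placement of summits, the listing of genes with peaks in lists with auxin and the tests on list length, enrichment and loss of summits in genes in this part were chosen after the results were seen. The test on rank, the question of a control list and both tests on splits were set before their results.

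Away from tRNA genes, centromeres and the 20 kb at chromosome ends, summits lay less often inside coding genes with auxin. The share inside coding genes was 88.3 ± 5.64% without and 64.4 ± 2.49% with auxin (SD, n = 3 each; exact permutation p = 0.1, the smallest possible), while coding genes make up 72.8% of nuclear bases. Between divergent genes, where promoters face each other, 45.3 ± 11.2 summits lay without and 146 ± 49.0 with auxin (SD, n = 3 each; exact permutation p = 0.1). Between convergent genes, where transcripts end, 27.7 ± 3.21 lay without and 9 ± 2 with auxin (SD, n = 3 each; exact permutation p = 0.1). Between tandem genes the numbers were 85.3 ± 18.8 and 145 ± 58.5 (SD, n = 3 each; exact permutation p = 0.2).

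Some listed genes had a peak in at least 2 lists with auxin and in at most 1 list without. At PRI2, which encodes a DNA primase subunit, peaks covered 41.2 ± 15.8% of the coding sequence with auxin (SD, n = 3) and none without. At GAL10 on chromosome II, repressed in glucose, all 3 lists with auxin and no list without it had a peak in the upstream window. PDS5, a cohesin regulator, and FLR1, a drug transporter, had one in 2 lists with auxin and none without. PDS5 was not among the genes counted as away from tRNA genes and centromeres, so a neighbour's peak can count for it. Peaks did not reach its coding sequence in any list. Among PAU genes, PAU9, PAU15, PAU18 and PAU6 had one in 3 of 3 lists with auxin and in none without. Within 20 kb of a chromosome end lay 101 ± 13.6 peaks without and 118 ± 18.0 with auxin, with overlapping groups (SD, n = 3 each; exact permutation p = 0.3). In lists of equal length the numbers were 49.3 ± 7.77 and 89.7 ± 11.7 (SD, n = 3 each; exact permutation p = 0.1).

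Peaks at most snoRNA genes and at part of the ribosomal protein genes were missing with auxin, and those at tRNA genes and centromeres were not, although the third list with auxin held 83 of 138 ribosomal protein genes and the share of these that kept a peak did not differ from other coding genes (42.3% against 49.7%, Fisher's exact test, adjusted p = 0.182). Shorter lists do not account for the pattern, since with 964 peaks in every list the share of ribosomal protein genes with a peak differed by -57.7 percentage points (auxin minus no auxin). Loss of the weaker peaks alone is argued against only for genes that ranked at or above the median tRNA gene without auxin. Of 133 such snoRNA and coding genes 51.1% kept a peak, against 135 of 135 tRNA genes. At that rank 6 of 27 snoRNA genes kept theirs, but 15 of 21 ribosomal protein genes did, or 71.4%. Of those with a peak in every list without auxin, only 27 of 71 snoRNA and 21 of 121 ribosomal protein genes ranked that high. Lower-ranked genes were not compared with tRNA genes of similar rank. Loss of weaker peaks therefore stays open for them, and so for most ribosomal protein genes. Signal over highly transcribed genes that does not come from Scc2 stays open, because 0 lists from untagged or no-antibody samples were used here. Loss of Med14, a change in transcription and an effect of auxin itself also stay open as untested explanations.

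With auxin, a larger share of summits lay between coding genes, and shorter lists do not account for this, since at equal length the share in coding genes differed by -25.7 percentage points (auxin minus no auxin). The number between coding genes differed by 142 (auxin minus no auxin) with a standard error of 65.1 (exact permutation p = 0.1). The closest lists were near each other, at 195 without and 200 with auxin. The rule for this number was changed after its values were seen, and an earlier form left it undecided. This number therefore does not decide whether loss of summits in genes alone accounts for the larger share. Loss of summits in genes alone is argued against between divergent genes. There 50, 89 and 144 summits with auxin lay outside every peak of the lists without auxin. Without auxin, 13, 9 and 7 such summits lay outside every peak of the lists with it. The difference was 84.7 with a standard error of 27.3. Higher enrichment in the lists with auxin cannot be told apart from a change in Scc2, since in only 2 pairs of lists were the median folds within 1.2 times of each other, both pairs held the third list without auxin, and the median ratio of summits between coding genes was 1.80. At 300 bp upstream of glycolysis and fermentation genes, 1.85 ± 3.21% of genes were covered without and 7.41 ± 12.8% with auxin (SD, n = 3 each; exact permutation p = 1), a difference within the spread between lists.

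Regrouping the 6 lists gives 10 splits, too few for a share under 0.05. The real split gave 453 regions held by all lists of one group and none of the other, which 1 of the 10 splits reached, the real one, and the highest other split gave 23. For classes that differed from other coding genes in the share kept, the real split gave 6 and the highest other split also gave 6, so that 2 of the 10 splits gave as many. Each of the other splits gave 3 to 6 classes, so the test called classes however the lists were grouped. The other split with 6 put the first and second lists without auxin together with the third list with auxin.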
